A study of Capsella rubella with 6 samples.

How the data were processed

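*Capsella rubella* is a self-fertilising plant of the mustard family. The samples were 2 leaf DNA samples, from the accessions Cr48.21 (Cr A) and Cr75.2 (Cr B), and 4 libraries of endosperm RNA. Endosperm is the seed tissue that carries 2 maternal genomes for 1 paternal genome. Per the labels' protocols, emasculated flowers were hand-pollinated after 2 days, seeds were taken 6 days after pollination, and each RNA replicate pooled the dissected endosperm of 300 to 500 seeds. There were 2 replicates of Cr A x Cr B and 2 of Cr B x Cr A. The labels do not say which partner was female, and names were read as female x male. The maternal share lay near the 2 to 1 dosage in all 4 libraries, but it cannot check that reading. Which base was maternal came from the authors' maternal and paternal counts, so the share is the same on either reading. With names read as male x female, Cr A and Cr B would change places in every result by accession of the allele.

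The submitters' processing notes name Trimmomatic, Bowtie 1.0 and TopHat, with no role or order. The genome build and the allele calling method were not given in the sources used here. For each endosperm library the authors deposited read counts per base at each listed SNP, with no header line. Every value in those columns was whole and at least 0. Another 2 tables, filed under the leaf DNA samples, cover the RNA of both crosses. Per the file headers they give maternal and paternal read counts per SNP, a gene interval and exon interval, a p-value per SNP, exon and gene, and a fraction, the maternal ratio, which in each gene equals maternal reads divided by 2 over that value plus paternal reads. Leaf DNA read counts were not analysed here.

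Those tables name the crosses only by a suffix. They were tied to the labelled libraries by site and count: read counts matched the corresponding library exactly at 99.99% of sites or more, and any of the 12 other pairings at 6.51% or fewer, or 0.365% at sites with 20 reads or more. They served as a map of SNPs to parental bases and gene intervals. Of 71169 mapped SNPs, 70761 could be assigned to a parental base. The parental base of 407 could not be determined and 1 had conflicting bases. Of those assigned, 53453 lay in gene intervals, 39402 of them in listed exons, and 17308 lay outside. The intervals covered 12621 genes with a median of 2 SNPs. Reads were then summed per gene, library and allele. A read that covers more than 1 SNP was counted at each, so these are base observations and not molecules. Calls of a base of neither parent made up about 0.1% of calls.

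Genes were given as scaffold, start, end and strand, as the authors' tables list them, without names. The files do not pair the intervals with names. The gene lists chosen before the data were examined covered Arabidopsis maternally and paternally expressed genes, Polycomb, DNA methylation, type I MADS-box, auxin, endosperm, seed coat and embryo genes. None could be matched to the intervals, so no result is given for them. In the text a gene is identified by its position.

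Parental bias was tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test on a maternal and a paternal column for each library. An offset set 2 maternal to 1 paternal as the null. The 8 columns were fitted with a term for each library, for the accession of the allele and for its parent, which left 2 residual degrees of freedom. Genes needed at least 20 allelic reads in each cross, and the Benjamini-Hochberg adjusted p threshold was 0.05. A gene was called maternally expressed when it also had a maternal share of at least 85% in each library, and paternally expressed at 50% or less in each library. The accession term of the same fit tested the Cr A against the Cr B allele, which is also the test of whether the parental ratio differs between the directions of the cross. Total expression was the sum of allelic reads per gene, compared between the crosses by edgeR with TMM normalisation and filterByExpr. Standard errors were the log2 estimate divided by the square root of its F statistic. Nothing says that replicates came from separate plants, so p-values measure the spread between these pooled samples.

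The named genes followed a rule set before the data were examined: the 10 genes in each direction of parental bias and the 5 in each direction of accession bias with the largest fitted log2 value among called genes with at least 50 allelic reads in every library. Because the intervals have no names, the text gives 2 per direction in full and summarises the others. Genes past the threshold in total expression were also to be named, and there were none. Binomial intervals are exact (Clopper-Pearson, 95%). A share of 0 is given with the limit set by 3 reads of the total over the 4 libraries. Intervals and limits cover counting error only.

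The parental and total tests were tested on counts simulated from these libraries. Of 100 genes with a simulated 2-fold parental change 62% were recovered, and 91% of those with a 4-fold change, with 12 of 8392 unchanged genes called. Unchanged genes were simulated at 2 to 1 in every library, so that count does not cover a maternal shift of a whole library. For total expression 1% of 2-fold and 4% of 4-fold changes were recovered. Alternatives included DESeq2 1.42.0, exact tests on summed reads, other read minimums, other nulls and size bounds, the deepest SNP per gene, thinned SNPs, exon SNPs alone, a block for the replicate number, and leaving out each library. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.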

Results

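Allele-specific expression was measured in the endosperm of reciprocal crosses between 2 accessions of *Capsella rubella*, Cr A and Cr B, at 6 days after pollination. The question was which genes are expressed mainly from the maternal or the paternal genome. Each direction of the cross had 2 libraries. Cr A x Cr B held 8122237 allelic reads in replicate 1 and 11701452 in replicate 2. Cr B x Cr A held 9524041 and 11636272. Of 12621 genes with a SNP, 8592 (68.1%) had enough reads in both crosses to be tested.

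Most genes were transcribed from both parental genomes, close to the 2 to 1 dosage of endosperm. The median maternal share of allelic reads per gene was 68.7% ± 1.17 (SD, n = 2) in Cr A x Cr B and 71.1% ± 1.69 (SD, n = 2) in Cr B x Cr A, against 66.7% for 2 to 1. The 4 libraries stood at 69.6% and 67.9%, then 69.9% and 72.3%. With 2 libraries against 2 an exact permutation test cannot give a two-sided p under 0.333, so the difference between the directions was not tested. Both libraries of Cr B x Cr A lay above both of Cr A x Cr B. In this design a difference between the directions cannot be told apart from one between the Cr A and Cr B alleles. The median log2 ratio of Cr A to Cr B over tested genes was -0.08. The middle 50% of genes lay between 61.0% and 74.2% in Cr A x Cr B replicate 2, the least maternal library, and between 66.3% and 78.6% in Cr B x Cr A replicate 2, the most maternal.

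**Figure D1:**
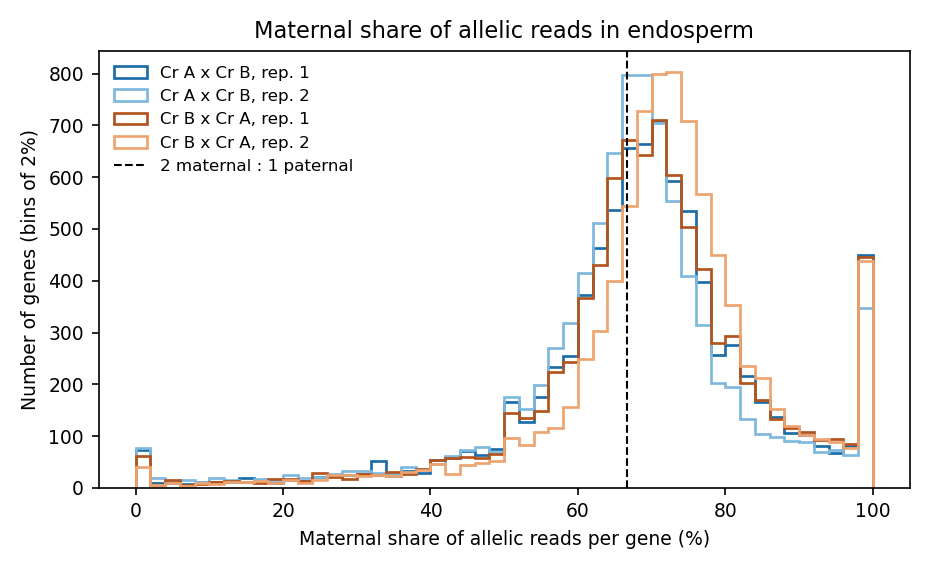
Maternal share of allelic reads per gene (x axis, %) against the number of genes in bins of 2% (y axis) for each of the 4 endosperm libraries, with a dashed line at 2 maternal to 1 paternal. Library medians lie between 67.9% and 72.3%, and a separate group of genes sits at the maternal end.

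A set of genes departed from this dosage in both directions of the cross, and more of them towards the maternal genome. There were 282 maternally expressed genes, 3.28% of those tested, and 73 paternally expressed genes, 0.85%. The median maternal share of the 282 genes was 98.8%, 133 had a mean share of at least 99%, and 49 had no paternal read in any library. The median maternal share of the 73 paternally expressed genes was 19.3%, with 18 genes at 10% or less and 62 at 33% or less. The bounds differ between the classes, at 85% or more and 50% or less, so these shares do not compare how complete the bias was. With bounds of 90% and 33%, 41 paternally expressed genes were left. Without the size bounds, 493 genes were more maternal and 139 less maternal than 2 to 1 at the adjusted threshold, 7.36% of genes tested. DESeq2 called 1000 and 243, and exact tests on reads summed per cross, which ignore the spread between replicates, 1090 and 237. At an unadjusted p under 0.05 the edgeR total was 1706.

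The maternally expressed gene with the largest fitted bias lay at scaffold 2, 725704 to 727162, minus strand. Its 7 SNPs gave 8064 maternal and 2 paternal reads (adjusted p = 7.91e-05, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). The next, at scaffold 3, 4590598 to 4593572, minus strand, had 1478 maternal reads and 0 paternal reads over 2 SNPs, which allows a paternal share of up to 0.203% (adjusted p = 0.000911, edgeR). Of the 10 named maternally expressed genes, 8 had no paternal read. Their fitted log2 values broadly followed their reads, from 11.05 at 1478 reads to 9.96 at 688, so the order does not rank strength of bias. The limits on their paternal share ran from 0.203% to 0.437%.

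The paternally expressed gene with the largest fitted bias lay at scaffold 7, 11097355 to 11102864, minus strand, with 15 SNPs. Its maternal share was 5.90% ± 7.54 (SD, n = 4), and its log2 deviation from 2 to 1 was -5.64 (SE 0.47, adjusted p = 0.00107, edgeR). The share was 1.28%, 2.05% and 3.12% in the first 3 libraries and 17.2% in Cr B x Cr A replicate 2. Among the named genes with a mean under 10%, the most strongly covered lay at scaffold 1, 11452090 to 11454311, plus strand, with 13569 to 26190 reads per library over 5 SNPs. Its maternal share was 8.51% ± 4.48 (SD, n = 4), with a log2 deviation of -4.57 (SE 0.21, adjusted p = 0.000117, edgeR). The mean maternal shares of the 10 named paternally expressed genes ran from 5.90% to 21.8%. The last of these, at scaffold 4, 8526546 to 8532043, had 46.9% maternal reads in Cr B x Cr A replicate 2 and between 10.5% and 16.2% in the others. Without Cr A x Cr B replicate 1 it no longer passed the threshold (adjusted p = 0.0536, edgeR).

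**Figure D2:**
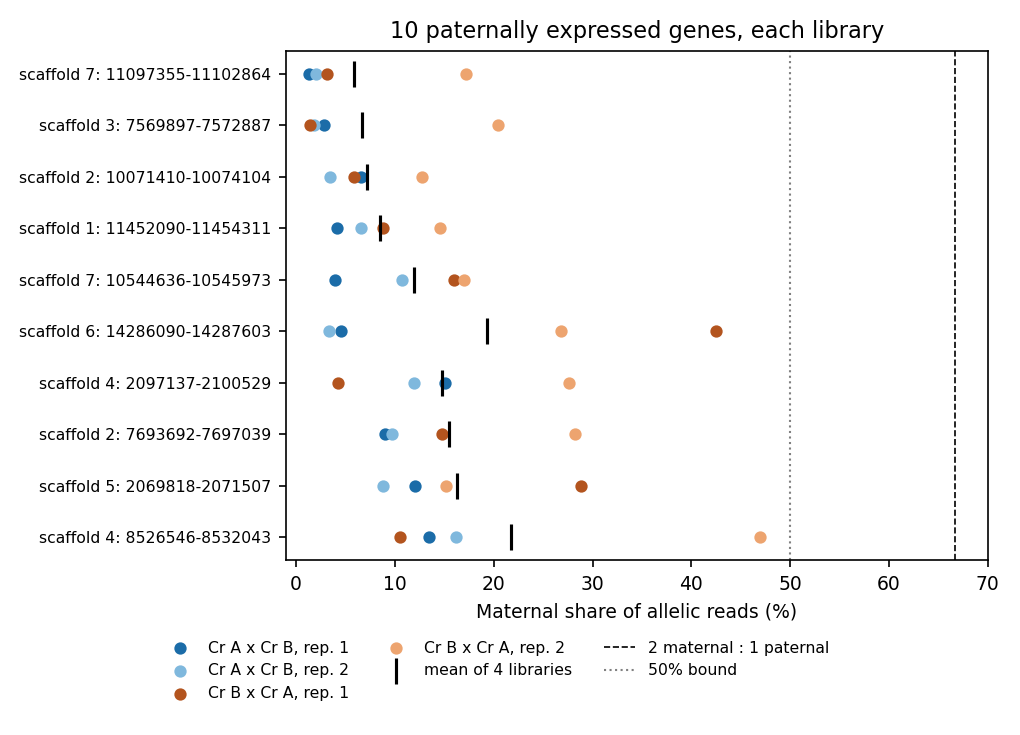
Maternal share of allelic reads (x axis, %) of the 10 named paternally expressed genes, given by scaffold, start and end (y axis). Points are single libraries, black bars are means of 4, the dotted line is the 50% bound and the dashed line is 2 maternal to 1 paternal. Means run from 5.90% to 21.8%, and Cr B x Cr A replicate 2 lies farthest right in 8 of the 10 genes.

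**Figure D3:**
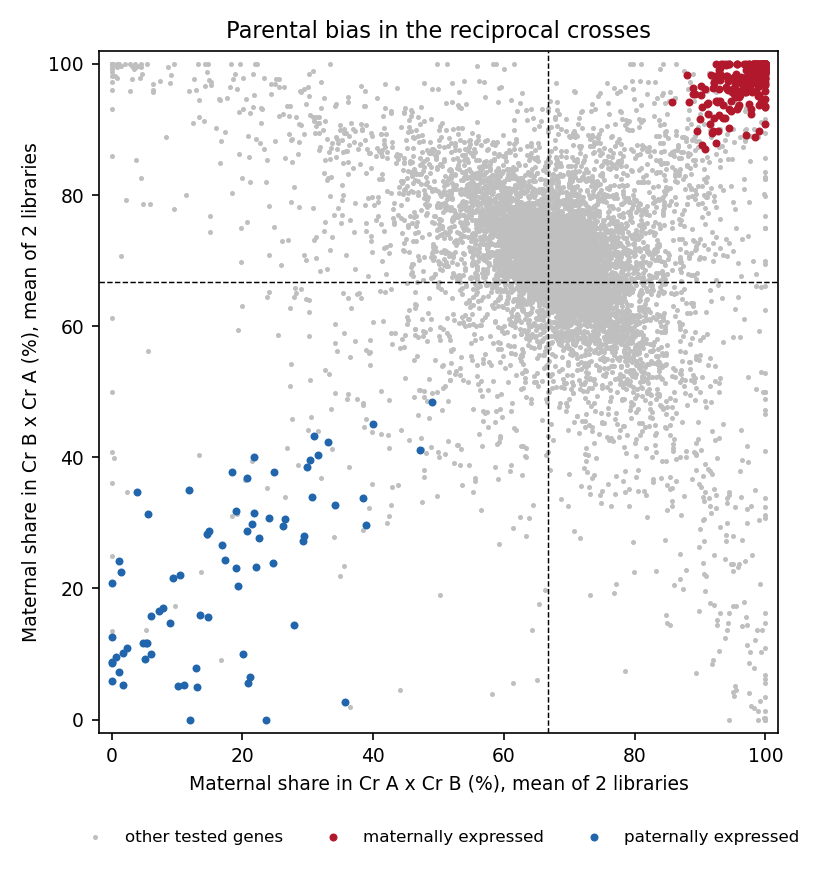
Mean maternal share in Cr A x Cr B (x axis, %) against that in Cr B x Cr A (y axis, %) for 8592 tested genes, with dashed lines at 2 maternal to 1 paternal. The 282 maternally expressed genes (red) are at the upper right and the 73 paternally expressed genes (blue) at the lower left. Genes with a bias towards 1 accession spread towards the other corners.

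Genes of both kinds occurred on each of the 8 largest scaffolds. Maternally expressed genes made up between 2.17% of tested genes on scaffold 3 and 4.49% on scaffold 4. Paternally expressed genes were most frequent on scaffold 2, with 15 of 903 tested genes (1.66%), and scaffold 8, with 13 of 834 (1.56%), and least frequent on scaffold 1, with 5 of 1355 (0.369%). The longest run of neighbouring maternally expressed genes held 4 genes at scaffold 5, 6012082 to 6031008, with a mean maternal share of 96.7%.

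**Figure D4:**
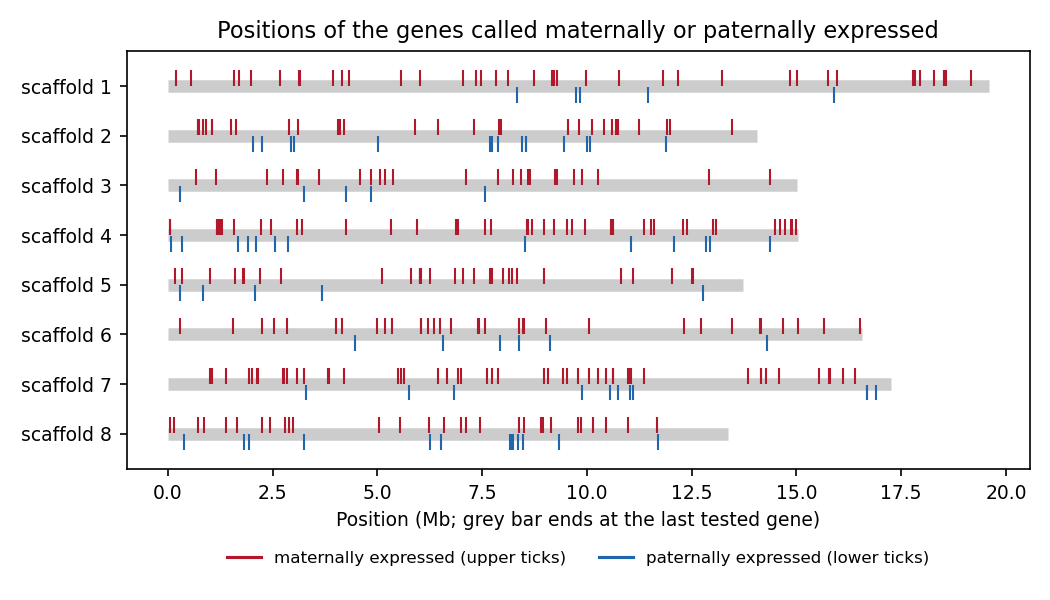
Positions in Mb (x axis) of maternally expressed genes (red, upper ticks) and paternally expressed genes (blue, lower ticks) on the 8 largest scaffolds (y axis). Grey bars end at the last tested gene. Scaffold 2 carries 15 paternally expressed genes, scaffolds 4 and 8 carry 13 each, and scaffolds 1, 3 and 5 carry 5 each.

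The authors' deposited tables give a p-value and a dosage-adjusted maternal ratio per gene. A p under 0.05 in both crosses and both replicates, with the ratio on the maternal side each time, was given to 452 genes in the authors' deposited tables, and 227 of the 282 maternally expressed genes were among them. On the paternal side the authors' deposited tables held 116 such genes, including 67 of the 73.

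Leaving out 1 library moved the counts of biased genes. Without Cr A x Cr B replicate 1, 306 genes in place of 493 were more maternal than 2 to 1. Without Cr A x Cr B replicate 2, 90 genes in place of 139 were less maternal. Transcripts of maternal seed tissue could not be removed, because no gene could be matched to a seed coat list.

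Expression also differed by the accession of the allele, tested with its parent in the same fit. This term averages over the directions, and the same sign in all 4 libraries was required only of the named genes. With cross names read as female x male, the Cr A allele was higher in 435 genes and the Cr B allele in 798. Together these were 14.4% of those tested (edgeR), and 254 and 407 of them differed by at least 2-fold. In 13 genes the Cr A allele made up at least 95% of reads in each library, and in 24 genes at most 5%. The gene with the largest fitted difference towards Cr A lay at scaffold 6, 13804520 to 13806933, plus strand, where all reads over 7 SNPs came from the Cr A allele. With a read counted at each SNP it covers, this allows a Cr B share of up to 0.337%, a limit that can be too low. The next, at scaffold 4, 6573366 to 6576696, minus strand, carried 99.9% ± 0.029 Cr A reads (SD, n = 4) with 2866 to 11877 reads per library. Fitted log2 values of these genes were nearly equal, at 10.88 (SE 0.49) and 10.87 (SE 0.27). Their order turned under some alternatives, such as the deepest SNP (8.93 and 9.16), and held under others. Towards Cr B, a gene at scaffold 7, 9381246 to 9384508, minus strand, had 0.078% ± 0.16 Cr A reads (SD, n = 4), and a gene at scaffold 3, 8755887 to 8756364, minus strand, had 0.092% ± 0.13. All 4 passed the edgeR test, with adjusted p between 6.80e-05 and 0.00168.

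The median gene had a log2 ratio of Cr A to Cr B of -0.08, and alignment to a reference closer to 1 accession would enter these values. DESeq2 called 769 and 1364 genes, and exact tests on summed reads 1880 and 3056. With the median ratio as the null in edgeR, 500 genes were higher from Cr A and 629 from Cr B. The counts fell without single libraries: to 195 and 400 without Cr A x Cr B replicate 1, and to 192 and 277 without Cr A x Cr B replicate 2. Without Cr B x Cr A replicate 2 the count for Cr B was 448. Of the 632 genes past the parental test, 74 also passed the accession test, including 8 of the 282 maternally and 3 of the 73 paternally expressed genes. Among all tested genes 14.4% passed the accession test. The called genes cannot be compared with that share. Their size bounds in every library remove genes whose parental ratio differs strongly between the directions, and they had fewer reads than tested genes.

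No gene differed in total expression between the directions of the cross at the adjusted threshold among 9036 genes tested. The smallest adjusted p was 0.413 (edgeR), and 123 genes (1.36%) had an unadjusted p under 0.05. That is less than this threshold would give if no gene differed and the libraries varied independently. DESeq2, fitted to 12621 genes without filterByExpr, called 8 genes higher and 16 lower in Cr B x Cr A. With no read filter edgeR called 3 and 2, and with a block for the replicate number 2 and 3. The edgeR test without a block recovered 4% of simulated 4-fold changes, so that test could mostly not detect changes of that size in these 4 libraries. The simulation drew each library independently, without the resemblance of same-numbered libraries described below. The other fits were not tried on simulated counts.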

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

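The tests of depth, of a shared batch, of unplaced scaffolds and of SNPs in genes picked by 1 SNP were chosen after related results were seen. The test at equal depth replaced one on deeply covered genes whose value was known. The other tests here were set beforehand. The 11 genes below were picked out because the accession term, a test of the difference in parental ratio between the directions of the cross, passed the adjusted threshold (edgeR) although the gene was called in every library.

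For the 8 maternally expressed genes the log2 difference of the Cr A from the Cr B allele was fitted beside the parental term. It was 0.79, 1.12, 2.05 and 3.51 towards Cr A, and -1.48, -0.92, -2.38 and -0.92 towards Cr B. The gene at scaffold 1, 17775338 to 17778418, had a mean maternal share of 88.0% in Cr A x Cr B and 98.3% in Cr B x Cr A. The gene at scaffold 4, 1180130 to 1180974, had 98.8% and 95.1%. The value of 3.51 rests on a gene with 8 reads in Cr B x Cr A replicate 1. The 3 paternally expressed genes all had a higher maternal share in Cr B x Cr A, with differences of -0.63, -2.04 and -1.83. That direction was not particular to them. Over 65 paternally expressed genes the median maternal share was 17.6% and 14.8% in replicates 1 and 2 of Cr A x Cr B. Over 66 such genes it was 21.3% and 24.6% in replicates 1 and 2 of Cr B x Cr A. The value of -2.04 rests on 9 reads in Cr B x Cr A replicate 1 and 21 in Cr A x Cr B replicate 1. At scaffold 2, 3008197 to 3012290, the maternal share was 21.8% in Cr A x Cr B and 40.0% in Cr B x Cr A. At scaffold 6, 14286090 to 14287603, it was 3.93% and 34.7%.

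SNPs outside the gene intervals also carried parental bias, in data that no comparison above used. Of 1442 such SNPs with at least 20 reads in every library, 108 (7.49%) had a maternal share of at least 85% in each, in 57 blocks, and 7 (0.49%) had 50% or less, in 6 blocks. Inside genes the shares of SNPs were 1.94% and 0.55%. SNPs within a transcript are not independent, so no test was made of the difference. The block with most SNPs lay at scaffold 4, 4995884 to 4998057, with 12 SNPs and a maternal share of 99.6% ± 0.11 (SD, n = 4). Blocks at scaffold 5, 6021894 to 6022863 and 6023982 to 6024709, lay within the span of the run of 4 maternally expressed genes on that scaffold. Some others lay beside called genes, such as scaffold 4, 1179953 to 1180068, beside the maternally expressed gene at 1180130 to 1180974. The SNP at scaffold 6, 8493142, lay beside the maternally expressed gene at 8493194 to 8493484. Blocks therefore need not be separate transcripts. The paternal block with most SNPs, at scaffold 11, 86483 to 86608, had a maternal share of 7.29% ± 9.68 (SD, n = 4).

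The excess of maternally over paternally expressed genes may hold RNA of maternal tissue carried over with the endosperm, which predicts a higher level of maternally expressed genes in the library of each cross with the higher genome-wide maternal share. Their level was higher there in Cr A x Cr B, by a median log2 of 0.83 (95% bootstrap interval over genes 0.59 to 1.06), and not measurably in Cr B x Cr A, at -0.080 (-0.28 to 0.16), and with 1 library on each side this is left open. Organelle transcripts aligned to unplaced scaffolds are argued against, since 1 of the 36 tested genes outside the 8 largest scaffolds was maternally expressed (2.78%, interval 0.070% to 14.5%), but organelle copies within the large scaffolds were not tested. Wrong bases at single SNPs are argued against as the general source in the genes that could be checked. Because their deepest SNP alone was at 85% maternal or more in every library, 211 genes were picked. Only 88 of them had enough reads at other SNPs at least 100 bp away. Of these 88, 83.0% (73, interval 73.4% to 90.1%) passed the same bound over those other SNPs. At the 50% bound 50 genes were picked, 29 could be checked and 25 passed. Within called genes every SNP passed in 70 of 99 maternally and 14 of 28 paternally expressed genes, and genes with 1 SNP could not be checked. Imprinting in endosperm, the biological explanation that the reciprocal design names, stays open beside carry-over.

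The maternal reads left in paternally expressed genes are a related pattern. Carry-over of maternal RNA predicts a higher share in the library of each cross with the higher genome-wide share. The median paired difference was 3.21 points over 65 of the 73 genes in Cr A x Cr B (95% bootstrap interval over genes 1.19 to 4.67) and 3.51 points over 66 genes in Cr B x Cr A (0.38 to 5.35). Each comparison sets 1 library against 1, so the intervals do not cover the spread between samples, and any cause that raises maternal reads across a whole library would give the same. Carry-over stays open, and incomplete silencing of the maternal allele was not tested.

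Libraries with the same replicate number resembled each other more than libraries of the same cross: over 9036 genes, which are not independent replicates, the correlation of log2 levels was 0.918 and 0.967 for equal numbers, and 0.902 and 0.858 within a cross. The lower depth of the replicate 1 libraries is argued against as the whole source. With all libraries thinned to equal reads, the lower correlation for equal numbers still exceeded the higher one within a cross, by 0.0169 (95% bootstrap interval over genes 0.0101 to 0.0240). Among genes with at least 1000 reads in every library the correlations were 0.852 and 0.934 for equal numbers and 0.832 and 0.728 within a cross, a gap of 0.0205 (-0.0048 to 0.048). All 4 libraries correlated best with the library of their own number, as a shared batch or a shared stage of the seeds could give, and the labels name neither.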

How the results depend on the processing

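Exon SNPs alone were an alternative chosen after seeing the data. The others were set before the data were examined. The 30 named genes kept their direction in each alternative computed for them, and 29 stayed past the threshold in all of them. The exception was the paternally expressed gene at scaffold 4, 8526546 to 8532043, without Cr A x Cr B replicate 1. With DESeq2 1000 genes were more and 243 less maternal than 2 to 1, and 769 were higher from Cr A and 1364 from Cr B. With exact tests on reads summed per cross, which ignore the spread between replicates, these were 1090 and 237, and 1880 and 3056. Bounds of 90% and 33% left 41 paternally expressed genes, and no bound gave 493 and 139, by construction. For total expression DESeq2 called 8 higher and 16 lower in Cr B x Cr A. It was fitted to 12621 genes, so the read filter was left out as well. With no read filter edgeR called 3 and 2, and with the block 2 and 3. The cause of these differences was not tested. The share of all allelic reads in Cr A x Cr B replicate 2 was 66.6%, below its median over genes; the cause was not tested. With each library's median as the null, 367 genes were more and 172 less maternal, with 248 maternally and 74 paternally expressed genes.

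Leaving out each library in turn assumed that the lone library of a cross varied like the others. It gave 306 to 424 genes more maternal and 90 to 129 less maternal, 222 to 266 maternally and 53 to 81 paternally expressed genes, 192 to 323 genes higher from Cr A, 277 to 660 higher from Cr B, and 0 to 0 in total expression. Fewer libraries were fitted, and fewer genes were tested in the allelic tests. The count more maternal fell to 306 without Cr A x Cr B replicate 1, and that less maternal to 90 without Cr A x Cr B replicate 2. For Cr A it was 195 and 192 without those libraries, and for Cr B 400 and 277, or 448 without Cr B x Cr A replicate 2. Replicate numbers are shared by only 2 pairs and the labels name no batch, so they were not taken as pairing; same-numbered samples deviated together across genes (r = 0.57). In the allelic fits the replicate block let the parental ratio differ between replicate numbers, so its parental test covers the replicate 1 libraries alone. That test gave 512 genes more and 108 less maternal. With the size bounds in all 4 libraries, 257 and 65 were maternally and paternally expressed. In the same fit 534 and 950 genes were higher from Cr A and Cr B. The maternal share without seed coat genes, the gene list tests and the leaf DNA description were not run. Depth limits the paternal share that a gene without paternal reads allows, 0.437% for the least covered of the 10 named, with a read counted at each SNP it covers.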

Other observations

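The tests of spread over the scaffolds were chosen after the counts per scaffold were seen; those of neighbouring genes were set beforehand. Relative to genes that pass no parental test, paternally expressed genes were at a higher level in replicate 2 than in replicate 1 of both crosses, by a median log2 of 0.25 in Cr A x Cr B (95% bootstrap interval over genes, 1 library against 1, 0.12 to 0.47) and 0.98 in Cr B x Cr A (0.49 to 1.55). Maternally expressed genes were lower in replicate 2 of Cr A x Cr B, at -0.83 (-1.07 to -0.58), and showed no measurable shift in Cr B x Cr A, at -0.080 (-0.27 to 0.16). Median reads per library were 125 for maternally expressed genes, 127 for paternally expressed genes and 275 for tested genes.

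Maternally and paternally expressed genes may be unevenly spread over the genome. For paternally expressed genes the counts on the 8 largest scaffolds departed from those of tested genes (permutation test of the chi-square statistic, 10000 draws, p = 0.002, adjusted over both classes 0.004). For maternally expressed genes the adjusted p was 0.0792, which leaves it open. Neighbouring genes within 10 kb were both maternally expressed in 8 pairs, against 6.38 in random draws (one-sided permutation p = 0.307), and both paternally expressed in 2 pairs, against 0.416 (p = 0.0652). The bound set beforehand, a count within the central 95% of the draws, was met in both cases, but it was a poor bound: the counting intervals of the observed pairs reach 15.8 and 7.22, above the upper ends of 12 and 2 of the draws. A modest excess of neighbours is therefore neither shown nor excluded.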
